A study of Homo sapiens with 9 samples.

How the data were processed

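The samples were 9 arrays of total RNA from MCF-7 cells, 3 each from untreated cells and from cells 1 h and 48 h after addition of tomato leaf extract at 5.85 µg/ml. Per the labels, untreated cells were harvested when partly confluent, extract was added at what is called confluent level, glossed as about exponential growth, and no solvent or time-matched control is named. The labels call the arrays replicates and do not say whether each came from a culture of its own, so the p-values measure the spread between these samples. Groups were taken from the sample titles and treatment labels.

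The deposited values are log2 signals, 1 per row and array, which the authors made from array scans in GeneSpring GX 7.2, per the labels and the series design text. Background correction, summarization and normalization are not stated. The log base is not stated either and was inferred from the values, whose largest is 13.45, which as a natural logarithm would exceed the range of a scanner. The design text names the Human Exon 1.0 ST array, while the annotation given for the row IDs is that of the Human Gene 1.0 ST platform. That annotation lists 21214 of the 33297 rows. Of these, 19460 name exactly 1 gene and 1754 name several, while 12083 rows are not listed. Symbols were updated through Entrez IDs in the RefSeq table of assembly GRCh38.p14, which found 19429 of them. No row was left out of the tests, and 18417 genes had a row of their own.

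Differences between groups were tested on the deposited values with limma 3.58.1 in R 4.3.3, with 1 linear model over all 9 arrays, moderated variances (prior degrees of freedom 2.13) and 3 contrasts. P-values were adjusted by the Benjamini-Hochberg method over 33297 rows for each contrast, with a threshold of 0.05, and an F test asked for any difference among the groups. Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, on 1 row per gene, the one with the highest mean signal, and adjusted over 31 lists. An estimated correlation served as an alternative. Of the lists, 27 were of pathways and 4 of cells that the culture should lack. They held 941 genes, 842 of them measured. For each list the number of members past the threshold was counted both adjusted over all rows and adjusted over the list alone. Per-array list means were compared by exact permutation, for which 0.1 is the smallest p that 3 against 3 arrays can give. The lists were immediate early genes, heat shock response, NRF2 and oxidative stress, unfolded protein response and ATF4 targets, p53 targets, apoptosis machinery, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, cholesterol synthesis and uptake, sterol efflux and LXR targets, fatty acid synthesis, estrogen receptor targets, AhR and xenobiotic targets, NF-kB and inflammatory genes, interferon response, cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation, proteasome, autophagy and lysosome, metallothioneins and metal response, extracellular matrix, luminal epithelial genes, quiescence and growth arrest, RNA and array quality, and markers of fibroblasts, leukocytes, endothelium and basal epithelium.

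Genes were named by a rule fixed before the data were examined, as were the tests and lists. Per contrast it takes, among rows naming exactly 1 gene, up to 10 higher and 10 lower that pass the threshold with no overlap between the groups, or the 5 highest and 5 lowest by moderated statistic where none pass. It adds up to 4 members of smallest p for each list that passed. In the contrast between 48 h and 1 h it takes only genes named by the other contrasts. HSPH1, RPL27, RPS7 and RPL13, members of lists that passed in that contrast, were named there outside the rule. Genes ranked next to SNORD38A at 48 h were named after their values were seen.

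Both steps were tested on simulated data in which 100 rows were shifted at each size. The spread of each row came from the fit to these arrays but was the same on all 9, and genes were drawn independently. Of rows shifted by a log2 difference of 1, 48% were called at 48 h against untreated, 44% at 1 h against untreated and 51% at 48 h against 1 h, with 11, 9 and 7 false calls over 33297 rows. At a log2 difference of 2 the shares were 88%, 90% and 92%. A mitosis list shifted by -0.25 was called in each of the 3 comparisons over 18417 genes, together with 0, 1 and 0 other lists. In the data the untreated arrays had a wider spread than the treated ones. Genes of a list were also correlated, with estimates of 0.26 for immediate early genes and 0.39 for the proteasome. The simulation therefore does not show which shares or false calls to expect here.

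Alternatives were quantile normalization, median centring, leaving out the dimmest 25% of rows, an intensity trend with a robust prior, a fit of 2 groups alone, a plain test without moderation, a replicate block, the mean of all rows of a gene, an estimated correlation and leaving out each array in turn. Array quality weights, rows naming 1 gene alone, and an estimated correlation without untreated replicate 2 were added after seeing the data. Splits of the arrays were refitted for each comparison, with 100 drawn for the F test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.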

Results

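MCF-7, an estrogen receptor-positive human breast cancer line, was profiled before and after treatment with an extract of tomato leaves. The extract was added at 5.85 µg/ml, and RNA was taken from untreated cells and from cells 1 h and 48 h after treatment. Each of the 3 groups had 3 arrays, 9 in all, and each array gave a log2 signal for 33297 rows, of which 19460 name exactly 1 gene. The labels name no cells given the solvent alone and no untreated cells kept for 48 h, so extract and time in culture changed together in both comparisons with untreated cells.

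Array medians lay between 3.43 and 3.53 on the log2 scale. Untreated replicate 2 stood apart from the rest. Its Pearson correlation with the other arrays, across rows of the table, was 0.783 to 0.816, against 0.928 to 0.969 among the other 8 arrays. Its values were also compressed, with an interquartile range of 1.16 against 1.58 to 1.75 on the others. The mean SD within a group was accordingly 0.38 among untreated arrays, 0.21 at 1 h and 0.19 at 48 h. Each list that passed is therefore given with its value without that array wherever the call ended or the median moved by over 1.5 times.

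**Figure D1:**
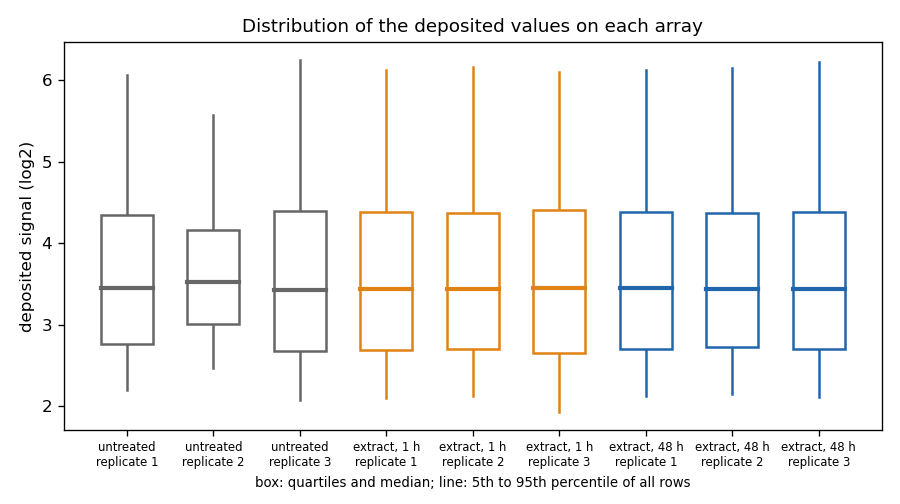
Signal of all rows on each of the 9 arrays, on the log2 scale on the vertical axis, with boxes for the quartiles and median and lines from the 5th to the 95th percentile. Untreated replicate 2 spans a narrower range, with a 95th percentile of 5.57, than the other arrays, whose 95th percentiles run from 6.06 to 6.25.

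The first comparison asked what differed in the cells 48 h after extract was added. Genes of mitosis and histone genes were lower than in untreated cells. Lists of DNA replication and of the proteasome also passed downward, but their untreated and 48 h arrays overlapped and their calls ended without untreated replicate 3. Immediate early, growth arrest, ribosomal protein and extracellular matrix genes were higher. Of 31 gene lists tested with camera, 14 passed, 8 upward and 6 downward, and 2 of these, both downward, also passed with an estimated correlation between genes, though not when untreated replicate 2 was left out as well. Among single rows, 1 of 33297 passed the limma test, SNORD38A, a small nucleolar RNA encoded in an intron of a ribosomal protein gene.

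The mitosis list fell at 48 h. Of its 39 measured genes, 32 were lower and 7 higher than in untreated cells, with a median log2 difference of -0.27 (camera, adjusted p = 3.5e-10; adjusted p = 0.0499 with an estimated correlation, and 0.131 when untreated replicate 2 was also left out). Relative to each gene's mean over all arrays, the list averaged 0.20 ± 0.06 on untreated arrays and -0.11 ± 0.04 at 48 h (SD, n = 3). Every 48 h array lay below every untreated array, for which the exact permutation p is 0.1, the smallest that 3 against 3 arrays allow. TOP2A, the topoisomerase that disentangles chromosomes, measured 4.32 ± 0.35 in untreated cells and 3.31 ± 0.14 at 48 h (log2, SD, n = 3). The differences of BUB1B, a spindle checkpoint kinase, HMMR, a spindle protein, and DLGAP5, a microtubule-binding protein, were -0.52 ± 0.13, -0.83 ± 0.23 and -0.62 ± 0.18 (log2, SE). None of the 39 genes passed over all rows, and 0 passed when adjusted over the list alone.

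Replication-dependent histone genes, which are transcribed mainly in S phase, also fell at 48 h. Of 43 measured, 31 were lower and 12 higher, with a median of -0.21 (adjusted p = 2.6e-05; adjusted p = 0.0499 with an estimated correlation, and 0.131 when untreated replicate 2 was also left out). The median was -0.11 without untreated replicate 2 (adjusted p = 5.7e-04). H3C1 and H3C2, both genes of histone H3, differed by -0.64 ± 0.14 and -0.54 ± 0.15 (log2, SE), and H2BC14 and H2BC10, genes of histone H2B, by -0.53 ± 0.19 and -0.48 ± 0.18. In the list of G1/S and DNA replication genes, 29 of 43 were lower and 14 higher, with a median of -0.10 (adjusted p = 0.0063; adjusted p = 0.463 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, differed by -0.99 ± 0.29, MCM5, part of the replicative helicase, by -0.97 ± 0.32, and RRM1, a subunit of ribonucleotide reductase, by -0.91 ± 0.34. This call ended without untreated replicate 3, when the median was -0.045 (adjusted p = 0.185), and the median was -0.06 without 48 h replicate 2 (adjusted p = 0.0127).

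The proteasome list fell, with 23 of 28 genes lower, 5 higher and a median of -0.23 (adjusted p = 2.6e-05; adjusted p = 0.463 with an estimated correlation). PSMB1 and PSMA5, subunits of the core particle, differed by -0.48 ± 0.11 and -0.89 ± 0.24 (log2, SE), and PSMC4 and PSMD4, of the regulatory particle, by -0.55 ± 0.16 and -0.65 ± 0.24. Relative to each gene's mean over all arrays, the list averaged 0.14 ± 0.46 on untreated arrays and -0.13 ± 0.06 at 48 h (SD, n = 3, exact permutation p = 0.4). The size of this shift rested on the untreated arrays, with a median of -0.13 without replicate 1 (adjusted p = 0.00765), -0.46 without replicate 2 (adjusted p = 4.2e-15) and -0.12 without replicate 3, when the call ended (adjusted p = 0.0517). Ribosome biogenesis genes had a median of -0.09, with 25 of 34 lower (adjusted p = 0.0033; adjusted p = 0.463 with an estimated correlation). Their call ended without untreated replicate 1 (median -0.11, adjusted p = 0.0779) or replicate 3 (median -0.09, adjusted p = 0.106), and the median was -0.15 without replicate 2 (adjusted p = 1.9e-06). In this list UTP4 and FBL, of ribosomal RNA processing, differed by -0.92 ± 0.25 and -0.70 ± 0.24. Cholesterol synthesis and uptake genes had a median of -0.16, with 13 of 20 lower (adjusted p = 0.0347; adjusted p = 0.279 with an estimated correlation). HMGCS1, which makes the substrate of HMG-CoA reductase, differed by -0.89 ± 0.34, while MVD, of the same pathway, differed by 0.70 ± 0.24. That call ended without any one of the untreated arrays, with medians of -0.14, -0.08 and -0.20 without replicates 1, 2 and 3 (adjusted p = 0.0779, 0.0628 and 0.0862). Without 48 h replicate 2 or 3 the median was -0.09 or -0.05 (adjusted p = 0.0414 and 0.0498).

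Immediate early genes, a class switched on within minutes by growth factors and stress, rose as a list at 48 h. Of 37 measured, 35 were higher and 2 lower, with a median of 0.27 (adjusted p = 4.0e-11; adjusted p = 0.279 with an estimated correlation). Of these, 8 genes passed when adjusted over the list alone and 0 over all rows. HBEGF, a ligand of the EGF receptor, went from 3.81 ± 0.28 to 5.04 ± 0.14 (log2, SD, n = 3; adjusted over the list alone, adjusted p = 0.00145). DUSP1, a phosphatase that inactivates MAP kinases, differed by 0.81 ± 0.11 (log2, SE), JUN, a subunit of AP-1, by 1.30 ± 0.25 and IER5 by 0.63 ± 0.13. Genes of quiescence and growth arrest rose too, with 23 of 27 higher and a median of 0.26 (adjusted p = 3.6e-06; adjusted p = 0.279 with an estimated correlation). BCL6, a transcriptional repressor, went from 4.24 ± 0.08 to 5.46 ± 0.27 and passed when adjusted over the list alone (adjusted p = 8.8e-04). TXNIP, an inhibitor of thioredoxin, differed by 1.07 ± 0.27, YPEL3 by 0.74 ± 0.21 and BTG1, an antiproliferative factor, by 1.26 ± 0.38. The median of the growth arrest list was 0.15 without untreated replicate 2 (adjusted p = 1.1e-04), and without 48 h replicate 1 it was 0.40 (adjusted p = 3.4e-06).

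Cytosolic ribosomal protein genes rose, with 48 of 56 higher, 8 lower and a median of 0.31 (adjusted p = 1.1e-06; adjusted p = 0.429 with an estimated correlation). RPL23, RPL27A, RPS19 and RPL23A differed by 0.60 ± 0.20, 0.55 ± 0.20, 0.73 ± 0.29 and 0.51 ± 0.22 (log2, SE). The median was 0.15 without untreated replicate 2 (adjusted p = 9.2e-05). The list of extracellular matrix, adhesion and EMT genes rose, with 26 of 35 higher and a median of 0.19 (adjusted p = 0.0021; adjusted p = 0.463 with an estimated correlation). SNAI1, a repressor of epithelial genes, differed by 0.60 ± 0.14 and TIMP3, an inhibitor of metalloproteinases, by 1.09 ± 0.24, and these 2 passed when adjusted over the list alone (adjusted p = 0.0365 for both). TGFBI and THBS1, both secreted matrix proteins, differed by 0.57 ± 0.15 and 0.83 ± 0.27. The median was 0.09 without untreated replicate 2 (adjusted p = 0.0231).

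The heat shock list rose, with 14 of 21 genes higher, 7 lower and a median of 0.23 (adjusted p = 0.0168; adjusted p = 0.463 with an estimated correlation). Its 4 leading chaperone genes passed when adjusted over the list alone, DNAJB1 at 0.87 ± 0.13, HSPA8 at 0.77 ± 0.13, CRYAB at 1.75 ± 0.38 and BAG3 at 0.56 ± 0.16 (log2, SE). Leaving out untreated replicate 1 or 3 ended the call (medians 0.22 and 0.24, adjusted p = 0.06 and 0.0517), and the median was 0.12 without replicate 2 (adjusted p = 0.0129) and 0.145 without 48 h replicate 1 (adjusted p = 0.0378). Genes of the unfolded protein response and ATF4 had a median of 0.25, with 27 of 37 higher (adjusted p = 0.002; adjusted p = 0.563 with an estimated correlation). Among them HSPA5, the main chaperone of the endoplasmic reticulum, differed by 0.82 ± 0.17, CEBPB by 1.68 ± 0.42 and DDIT3, the stress factor CHOP, by 0.94 ± 0.24. Without untreated replicate 2 the median was 0.10 and the call ended (adjusted p = 0.177). Autophagy and lysosome genes had a median of 0.10, with 28 of 38 higher (adjusted p = 0.0328; adjusted p = 0.563 with an estimated correlation). GABARAPL2, an autophagosome protein, differed by 1.40 ± 0.40 and the lysosomal protease gene CTSD by 0.66 ± 0.22. This call ended without untreated replicate 1, untreated replicate 2 or 48 h replicate 1, with medians of 0.10, 0.06 and 0.10 (adjusted p = 0.0779, 0.177 and 0.0932). NF-kB and inflammatory genes had a median of 0.08, with 17 of 28 higher (adjusted p = 0.0408; adjusted p = 0.429 with an estimated correlation), among them TNIP1 at 0.52 ± 0.12 and REL at 0.58 ± 0.16. The NF-kB call ended without any of 5 arrays, namely untreated replicates 1 and 3, 1 h replicates 2 and 3 and 48 h replicate 3, with adjusted p from 0.0624 to 0.199 and medians from 0.06 to 0.13.

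Bright rows as a class were higher against untreated arrays, largely through untreated replicate 2. At 48 h random lists matched to the immediate early genes had a median of 0.15, or 0.02 without that array. Each passing list was therefore also set against 10000 random lists of the same size and mean signal, a check chosen after the data were seen. Of the 14 lists that passed at 48 h, 12 had medians outside the central 95% of the random lists. The NF-kB list and the autophagy list lay inside it, at percentiles 94.2 and 83.6. When untreated replicate 2 was left out, 11 lay outside and 3 inside, the third being cholesterol (percentile 3.04). At 48 h 7 of the 14 lists had every 48 h array on one side of every untreated array, namely the lists of mitosis, histones, cholesterol, immediate early genes, heat shock, NF-kB and growth arrest. The exact permutation p of the list means was 0.1 for each of these and 0.2 for unfolded protein response, ribosomal protein, autophagy and matrix lists. It was 0.4 for DNA replication, ribosome biogenesis and the proteasome. Over all 31 lists 8 had the 2 groups fully separated, against 3.1 expected by chance.

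Lists of several other pathways did not pass at 48 h. The p53 target list had a median of -0.01 (adjusted p = 0.921) and the apoptosis machinery -0.01 (adjusted p = 0.576). Estrogen receptor targets, which MCF-7 cells express, had a median of 0.07 (adjusted p = 0.921), and luminal epithelial genes 0.06 (adjusted p = 0.63). Medians were 0.01 for NRF2 and oxidative stress genes (adjusted p = 0.41), 0.07 for AhR and xenobiotic targets (adjusted p = 0.41) and -0.05 for the interferon response (adjusted p = 0.137). Among metabolic lists, medians were 0.17 for sterol efflux and LXR targets (adjusted p = 0.48), -0.03 for fatty acid synthesis (adjusted p = 0.218), 0.09 for glycolysis and hypoxia (adjusted p = 0.218) and -0.01 for oxidative phosphorylation (adjusted p = 0.567). Metallothionein and metal response genes had a median of 0.01 (adjusted p = 0.521), and genes of RNA and array quality 0.10 (adjusted p = 0.629). Markers of cells that a culture of this line should lack did not pass either, with medians of 0.04 for fibroblast, -0.02 for leukocyte, 0.07 for endothelial and 0.03 for basal epithelial markers (adjusted p = 0.41, 0.315, 0.921 and 0.787). The test and the median differed in sign for the lists of NRF2, p53 and basal markers, and the test and the mean for those of apoptosis, oxidative phosphorylation and endothelial markers. Without untreated replicate 2, fatty acid synthesis (median -0.08, adjusted p = 0.0023) and oxidative phosphorylation (median -0.11, adjusted p = 0.00495) passed downward. Other medians moved too without that array, to -0.18 for RNA and array quality, -0.05 for glycolysis and hypoxia, -0.11 for NRF2, -0.05 for apoptosis, 0.04 for estrogen receptor targets and -0.02 for basal markers. Those of sterol efflux, interferon, metallothionein, luminal, endothelial and leukocyte lists came within 0.02 of 0.

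**Figure D2:**
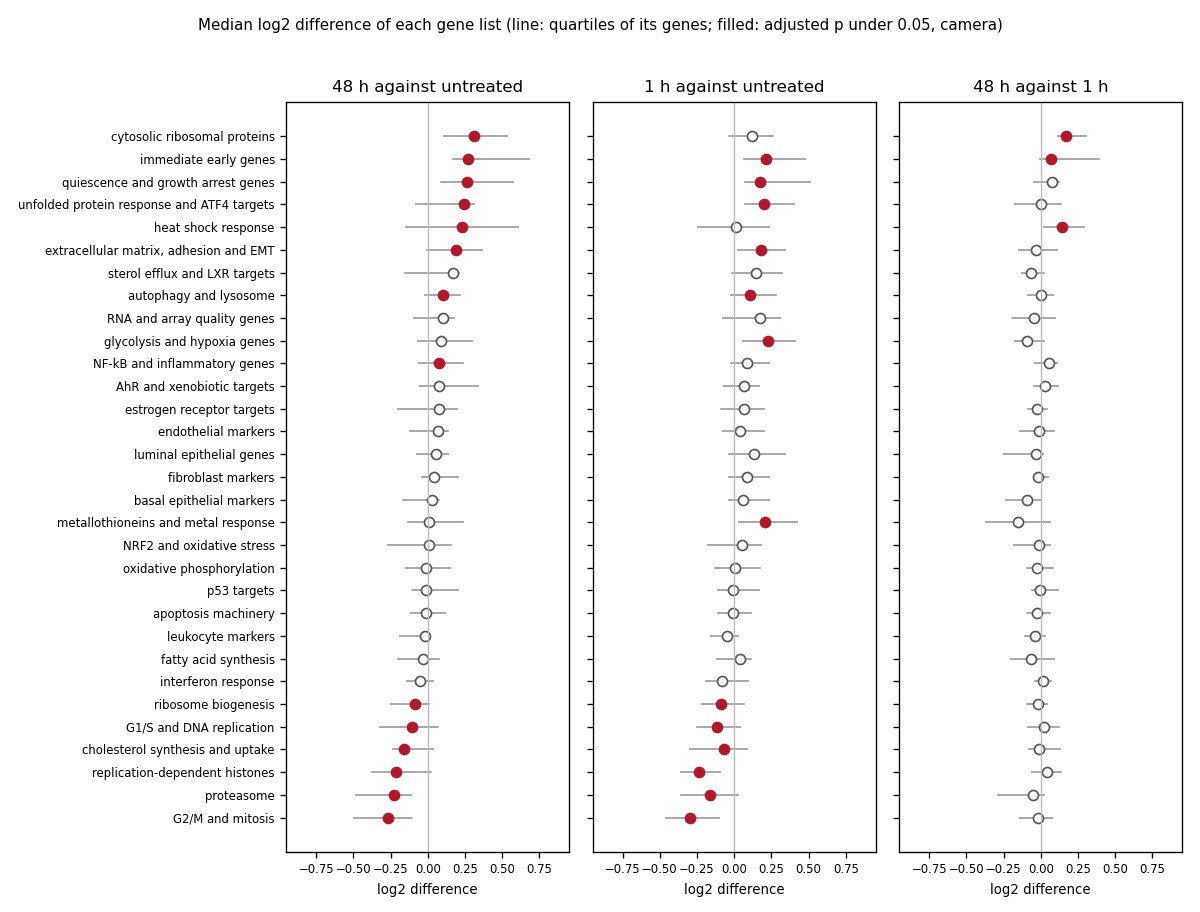
Median log2 difference of each of the 31 gene lists, on the horizontal axis, in the 3 comparisons, with lines for the quartiles of the list's genes and filled points where the camera adjusted p was under 0.05. At 48 h against untreated cells 14 lists are filled, at 1 h 13, and at 48 h against 1 h 3.

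SNORD38A was the single row past the limma test at 48 h. Its signal was 3.87 ± 0.11 in untreated cells and 5.73, 6.01 and 6.25 on the 3 arrays at 48 h (log2; SD, n = 3), a rise of 2.13 ± 0.16 (SE) or 4.38-fold (adjusted p = 0.0303). Leaving out any one of the 9 arrays ended this call, with adjusted p from 0.0583 to 0.356 and differences from 2.003 to 2.26. With a replicate block in the limma fit the adjusted p was 0.323. At an unadjusted p under 0.05, 1182 rows were higher and 1054 lower, against 1664.85 expected in all by chance, and in 9.24% of rows the 2 groups did not overlap, against 10% by chance. The total of 2236 was 5286 without untreated replicate 3, and 1427 and 1358 without 48 h replicates 2 and 3. With these 2 groups alone in the fit it was 1520, below the number expected by chance. Among the rows next in rank, chosen after their values were seen and not past the test, BCL6, HBEGF, DUSP1 and HYCC2 were highest (adjusted p = 0.222). The lowest were H2AC21, a histone H2A gene, at -0.67 ± 0.09 and EXOC1, of the exocyst, at -1.23 ± 0.17 (adjusted p = 0.222), followed by MTCH2, PYGO1 and TASOR.

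**Figure D3:**
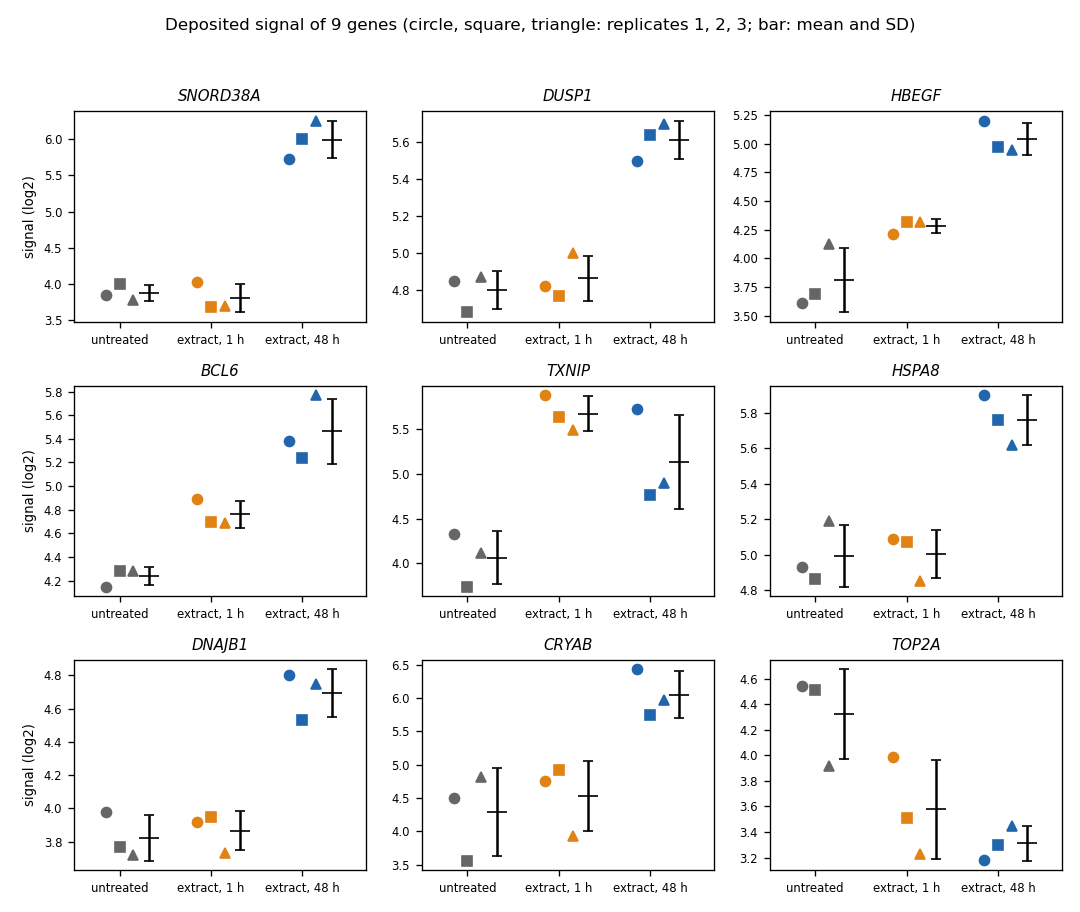
Signal of 9 genes on each array, on the log2 scale on the vertical axis, by group, with a marker per replicate and a bar for the mean and SD. SNORD38A, DUSP1, HSPA8 and DNAJB1 were higher on each 48 h array than on each array of the other 2 groups, while TXNIP was higher at 1 h and at 48 h than in untreated cells.

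The second comparison asked what differed 1 h after the extract was added. No row passed the limma test, with a smallest adjusted p of 0.651. At an unadjusted p under 0.05, 801 rows were higher and 1072 lower, in all 1873, or 5477 without untreated replicate 3. With these 2 groups alone in the fit the total was 1023, below the 1664.85 expected by chance. Of the 31 lists, 13 passed, 7 upward and 6 downward, and 2 of these, mitosis and the histones as at 48 h, also passed with an estimated correlation, though not when untreated replicate 2 was left out as well. Of the lists that passed, 11 did so at both times in one direction, but both comparisons use the same untreated arrays, and the number to be expected from that alone was not computed.

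Of the 39 genes of mitosis, 34 were lower and 5 higher at 1 h, with a median of -0.30 (adjusted p = 3.6e-11; adjusted p = 0.0326 with an estimated correlation, and 0.085 when untreated replicate 2 was also left out). The list averaged -0.09 ± 0.10 on the 1 h arrays, all below the untreated arrays (SD, n = 3; exact permutation p = 0.1, the smallest possible). TOP2A differed by -0.75 ± 0.23 (log2, SE), HMMR by -0.70 ± 0.23, and NDC80 and NUSAP1, of the kinetochore and spindle, by -0.47 ± 0.15 and -0.45 ± 0.15. Of the 43 histone genes, 36 were lower and 7 higher, with a median of -0.24 (adjusted p = 1.7e-08; adjusted p = 0.023 with an estimated correlation, and 0.085 when untreated replicate 2 was also left out), among them the linker histone gene H1-3 at -0.59 ± 0.17. For DNA replication genes 30 of 43 were lower and the median was -0.12 (adjusted p = 5.8e-04; adjusted p = 0.475 with an estimated correlation), with PCNA at -1.10 ± 0.29 and UHRF1, which maintains DNA methylation, at -0.72 ± 0.23. Without untreated replicate 3 this median was -0.01 and the call ended (adjusted p = 0.0894), and without 1 h replicate 2 the median was -0.07 (adjusted p = 0.0042).

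Proteasome genes had a median of -0.16 at 1 h, with 19 of 28 lower (adjusted p = 0.0021; adjusted p = 0.592 with an estimated correlation), PSMB1 differing by -0.51 ± 0.11. Their median was -0.40 without untreated replicate 2 (adjusted p = 3.1e-13). The proteasome call ended without untreated replicate 1 or 3 or 1 h replicate 3, with medians of -0.09, -0.10 and -0.05 (adjusted p = 0.102, 0.275 and 0.171). Ribosome biogenesis genes had a median of -0.09, with 23 of 34 lower (adjusted p = 0.0045; adjusted p = 0.475 with an estimated correlation). That call ended without untreated replicate 1 or 3 (medians -0.10 and -0.07, adjusted p = 0.102 and 0.18), and the median was -0.14 without replicate 2 (adjusted p = 3.1e-07). Cholesterol genes had a median of -0.07, with 12 of 20 lower (adjusted p = 0.0318; adjusted p = 0.368 with an estimated correlation) and HMGCS1 at -1.02 ± 0.34. The cholesterol call ended without untreated replicate 1 or 3 or 1 h replicate 2 or 3, with medians from -0.09 to -0.01 and adjusted p from 0.0859 to 0.138, and the median was -0.14 without 1 h replicate 1 (adjusted p = 0.0127).

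Immediate early genes were higher at 1 h, with 32 of 37 above untreated cells and a median of 0.22 (adjusted p = 4.0e-05; adjusted p = 0.475 with an estimated correlation). FOS, a subunit of AP-1, measured 4.78 ± 0.69 in untreated cells and 6.01 ± 0.27 at 1 h (log2, SD, n = 3), and JUNB and HBEGF differed by 0.65 ± 0.17 and 0.47 ± 0.15 (SE). The median was 0.12 without untreated replicate 2 (adjusted p = 6.9e-04). For the growth arrest list 21 of 27 genes were higher and the median was 0.17 (adjusted p = 7.8e-04; adjusted p = 0.475 with an estimated correlation), or 0.06 without untreated replicate 2 and 0.265 without untreated replicate 3 (adjusted p = 0.0171 and 6.5e-04). TXNIP had the highest moderated statistic of any named gene at 1 h. It went from 4.06 ± 0.30 to 5.67 ± 0.20 (log2, SD, n = 3), a difference of 1.61 ± 0.27 (SE), which passed when adjusted over the list alone (adjusted p = 0.00869) but not over all rows (adjusted p = 0.69). The unfolded protein response list had a median of 0.20, with 33 of 37 higher (adjusted p = 2.7e-04; adjusted p = 0.475 with an estimated correlation), or 0.09 without untreated replicate 2 and 0.325 without untreated replicate 3 (adjusted p = 0.0322 and 2.8e-04). In it DNAJB9, HSPA5 and ATF4 differed by 0.46 ± 0.14, 0.53 ± 0.17 and 0.75 ± 0.25.

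Extracellular matrix genes had a median of 0.18 at 1 h, with 27 of 35 higher (adjusted p = 0.00105; adjusted p = 0.475 with an estimated correlation), and THBS1 differed by 1.26 ± 0.27 (log2, SE). That call ended without 1 h replicate 1 (median 0.14, adjusted p = 0.0635), and the median was 0.28 without untreated replicate 3 (adjusted p = 0.00504). Glycolysis and hypoxia genes had a median of 0.23, with 29 of 34 higher (adjusted p = 0.0088; adjusted p = 0.592 with an estimated correlation), with EPAS1, a hypoxia-inducible factor, at 0.54 ± 0.18 and VEGFA, an angiogenic growth factor, at 0.67 ± 0.27. The glycolysis call ended without untreated replicate 2, when the median was 0.01 (adjusted p = 0.838), and without 1 h replicate 1 (median 0.16, adjusted p = 0.0695). Without untreated replicate 1 or 3 the glycolysis median was 0.36 or 0.38 (adjusted p = 0.0012 and 0.0217). Metallothionein and metal response genes had a median of 0.21, with 11 of 15 higher (adjusted p = 0.0216; adjusted p = 0.475 with an estimated correlation), including MT1B at 0.65 ± 0.24 and the zinc exporter gene SLC30A1 at 0.59 ± 0.22. The metallothionein call ended without untreated replicate 1 or 3 or 1 h replicate 1, with medians of 0.24, 0.21 and 0.16 (adjusted p = 0.0646, 0.0617 and 0.0986). Autophagy genes had a median of 0.11, with 27 of 38 higher (adjusted p = 0.0169; adjusted p = 0.545 with an estimated correlation), among them ULK1, an autophagy kinase, at 0.44 ± 0.12. The autophagy call ended without any of 4 arrays, untreated replicates 1 and 2 and 1 h replicates 1 and 2, with adjusted p from 0.0697 to 0.146 and medians from 0.08 to 0.12.

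Of the 13 lists that passed at 1 h, 8 had medians outside the central 95% of random lists of matched signal. Those of immediate early, growth arrest, matrix, metallothionein and autophagy genes lay inside, at percentiles 91.0, 85.1, 96.5, 92.0 and 81.6, a result that rested on untreated replicate 2. Without it 11 of the 13 lay outside, and the 2 inside were growth arrest (percentile 92.2) and glycolysis (percentile 51.4). Every 1 h array lay on one side of every untreated array for 4 of the 13, the lists of mitosis, histones, cholesterol and growth arrest. The exact permutation p of the list means was 0.1 for these and 0.2 for immediate early, unfolded protein response, DNA replication and metallothionein lists. It was 0.3 for autophagy and matrix, 0.5 for glycolysis and 0.6 for ribosome biogenesis and the proteasome. Heat shock and ribosomal protein genes did not pass at 1 h, with medians of 0.01 and 0.12 (adjusted p = 0.615 and 0.477), or -0.04 and -0.03 without untreated replicate 2 (adjusted p = 0.47 and 0.181). Without untreated replicate 2, lists of fatty acid synthesis and oxidative phosphorylation passed downward and that of luminal genes upward at 1 h (adjusted p = 0.0138, 0.002 and 0.0353). By rank of the moderated statistic, and not past the test, the highest rows after TXNIP were SLC44A4, ELAPOR1, LINC02370 and THBS1. The lowest were H2AC21, SNRNP40, ZNF717, SNORD13P1 and CYLC1, with H2AC21 at -0.74 ± 0.09 (adjusted p = 0.651).

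**Figure D4:**
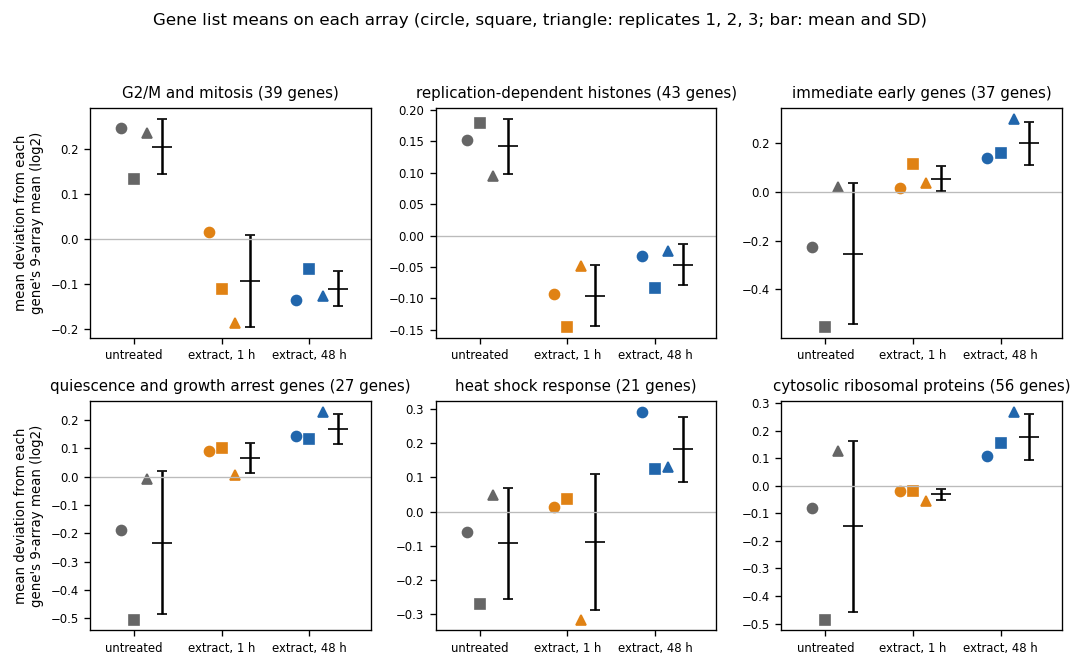
Mean deviation of 6 gene lists on each array, as the log2 difference from each gene's mean over all 9 arrays on the vertical axis, with a marker per replicate and a bar for the group's mean and SD. The mitosis and histone lists lie lower on all treated arrays than on all untreated arrays, while heat shock and ribosomal protein lists lie higher on each 48 h array than on each 1 h array.

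The third comparison set the 2 treated times against each other and does not use the untreated arrays as a baseline. Heat shock, immediate early and ribosomal protein genes were higher at 48 h than at 1 h. These were the 3 lists of 31 that passed, all upward, and none passed with an estimated correlation. Of 21 heat shock genes, 17 were higher and 4 lower, with a median of 0.14 (adjusted p = 1.5e-05; adjusted p = 0.83 with an estimated correlation). DNAJB1 went from 3.87 ± 0.12 to 4.69 ± 0.14 and HSPA8, a constitutive cytosolic chaperone, from 5.00 ± 0.13 to 5.76 ± 0.14 (log2, SD, n = 3). CRYAB and HSPH1 differed by 1.51 ± 0.38 and 1.28 ± 0.37 (SE), and these 4 genes passed when adjusted over the list alone. The call ended without 1 h replicate 3, when the median was 0.065 (adjusted p = 0.119), and the median was 0.21 without 1 h replicate 2 (adjusted p = 3.1e-07).

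Of 56 ribosomal protein genes, 53 were higher and 2 lower at 48 h than at 1 h, with a median of 0.17 (adjusted p = 7.6e-09; adjusted p = 0.83 with an estimated correlation). RPL27A, RPL27, RPS7 and RPL13 differed by 0.72 ± 0.20, 0.35 ± 0.11, 0.35 ± 0.14 and 0.44 ± 0.20 (log2, SE), and 0 of the 56 passed when adjusted over the list alone. Of 37 immediate early genes, 27 were higher, with a median of 0.07 (adjusted p = 7.3e-05; adjusted p = 0.83 with an estimated correlation). DUSP1 and HBEGF passed when adjusted over the list alone, at 0.75 ± 0.11 (adjusted p = 0.00561) and 0.76 ± 0.15 (adjusted p = 0.0202). The immediate early median was 0.14 or 0.13 without 1 h replicate 2 or 3, and 0.11 or 0.10 without 48 h replicate 1 or 2 (adjusted p at most 0.002). For all 3 lists every 48 h array lay above every 1 h array, and the median lay above the central 95% of random lists of matched signal. The lists of mitosis, DNA replication, histones and the proteasome had medians of -0.02, 0.02, 0.04 and -0.055 between the times and did not pass (adjusted p = 0.886, 0.786, 0.356 and 0.23).

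Among single rows SNORD38A again was the one that passed, at 3.80 ± 0.19 at 1 h and 5.73, 6.01 and 6.25 on the 3 arrays at 48 h (log2; SD, n = 3), a difference of 2.20 ± 0.16 (SE; adjusted p = 0.0236). Leaving out any of 8 arrays ended the call, with adjusted p from 0.0505 to 0.312, and it held without untreated replicate 2 (adjusted p = 0.0355). With a replicate block in the limma fit the adjusted p was 0.532. At an unadjusted p under 0.05, 459 rows were higher and 357 lower, in all 816 against 1664.85 expected by chance. The total was 1693 without untreated replicate 2 and 1648 with these 2 groups alone in the fit. An F test across the 3 groups also called 1 row (smallest adjusted p = 0.0313), with 1501 rows at an unadjusted p under 0.05.

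The 2 comparisons with untreated cells share their 3 untreated arrays. No row was called in both. Their log2 differences correlated across rows with r = 0.76. Simulated unchanged groups against shared simulated untreated arrays, with 1 spread for all groups, gave 0.499 on average and at most 0.517. That setting does not match these data, in which untreated arrays had a mean SD of 0.38 against 0.21 and 0.19. No correlation with each group's own spread is given, so 0.76 cannot be read as an excess over the shared arrays. The covariance was 0.0951, against 0.0375 in the simulation and 0.0858 expected from the variance of the untreated arrays alone. Without untreated replicate 2 the correlation was 0.641 and the covariance 0.0519. At an unadjusted p under 0.05, 296 rows were higher at both times and 420 lower, against 28.4 and 33.9 for independent lists, which ignores the shared arrays. Simulated unchanged groups against shared arrays gave 203.2 and 206.6 on average with 1 spread for all groups, and 620.4 and 625.5 with each group's own spread, so the observed counts lay above the first and below the second. Without untreated replicate 2 the counts were 257 and 663, for which no simulation was run. With 3 untreated arrays no split into parts of at least 2 is possible, and the correlation and these counts may come in large part from the shared arrays.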

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

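The tests of single arrays, of the untreated cultures, of signal level and of small RNA in this part were chosen after the results they concern had been seen, while the splits of the arrays were planned.

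The effects at 48 h and 1 h differed, by the direct contrast between the times, for 3 lists and 1 row. The median log2 difference at 48 h minus 1 h was 0.0667 for immediate early genes (limma camera, adjusted p = 7.3e-05), 0.14 for the heat shock response (adjusted p = 1.5e-05) and 0.17 for cytosolic ribosomal proteins (adjusted p = 7.6e-09). None of these passed with an estimated correlation (adjusted p = 0.83). For SNORD38A the difference was 2.20 (limma, adjusted p = 0.0236).

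For the lists higher at 48 h than at 1 h, the tables argue against a shift that depends on signal level, since 3 of 3 medians lay above the central 95% of 10000 random lists matched on mean signal. Of 18 fits that left out an array, 1 lost a call, that of heat shock without 1 h replicate 3 (median 0.065, camera, adjusted p = 0.119). The heat shock mean of that array was -0.32, against 0.01 and 0.04 on the other 1 h arrays, so one array as the source stays open for this list. For immediate early and ribosomal protein genes the calls held in each of these fits, which argues against one array of the 6 as their source. Correlation among the genes of a list, time in culture and a later effect of the extract stay open, because the labels name no untreated cells kept for 48 h.

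The lists of mitosis, DNA replication, histones and the proteasome were lower at both times. Without the untreated array that stands apart, 8 of 8 list comparisons passed downward at the preset correlation. With an estimated correlation as well, only DNA replication at 1 h passed (camera, adjusted p = 0.0491). For mitosis, DNA replication and the proteasome that array's list mean lay below those of the other untreated arrays. In these lists it pulled against the fall of the mean, so leaving it out was no test of it as the source. The median of the mitosis list did shrink without that array, from -0.267 to -0.255 at 48 h and from -0.30 to -0.22 at 1 h. For histones its mean was the highest (0.18 against 0.15 and 0.09), and the fall without it argues against that array as the source there. A shift that depends on signal level is argued against, with 8 of 8 medians below the central 95% of random lists of matched signal. The calls for DNA replication and the proteasome nevertheless ended without untreated replicate 3 at both times (adjusted p = 0.185 and 0.0517 at 48 h, 0.0894 and 0.275 at 1 h). At 1 h that of the proteasome also ended without untreated replicate 1 or 1 h replicate 3 (adjusted p = 0.102 and 0.171). The state of the untreated cultures at harvest and an effect of the extract cannot be told apart. Of the 4 lists, 0 passed as lower at 48 h than at 1 h, which does not show that the treated times were alike. For mitosis and histones most of the difference lay between untreated and treated cultures. Their list means were 0.20 and 0.14 on untreated arrays, -0.09 and -0.10 at 1 h and -0.11 and -0.05 at 48 h. The proteasome list averaged 0.14 on untreated arrays, -0.01 at 1 h and -0.13 at 48 h. No culture given the solvent alone is named that would separate handling from extract. The labels describe confluence in different words for untreated and treated cells, and a difference in confluence, which bears on cell cycle genes, was not tested.

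SNORD38A and other small nucleolar RNA rows were higher at 48 h than at 1 h. The 173 rows had a median of 0.15, with 138 higher and 34 lower. One array of the 6 is argued against as the source, since the lowest 48 h array lay 0.0722 above the highest 1 h array in its median deviation. Nesting in ribosomal protein genes stays open, since the 31 nested rows rose but so did the 142 others. Nested rows had a median of 0.22, with 25 higher (limma camera, unadjusted p = 4.7e-12, and 0.0024 with an estimated correlation). The others had a median of 0.14, with 113 higher (unadjusted p = 1.2e-13, and 0.0568 with an estimated correlation). Host genes were found by symbol, which left out RPSA, FAU and UBA52, so any rows nested in these counted among the others. Uneven recovery of short RNA may contribute, since the 173 rows of microRNA genes, which are as short, also rose (median 0.06, 105 higher; unadjusted p = 0.00575, and 0.292 with an estimated correlation). A biological change in these RNAs is therefore not separated from RNA isolation.

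Splits of the arrays into other groups of 3 are too few, at 10 per comparison, for a share under 0.05. At 48 h against untreated 2 of 10 splits gave as many rows (real 1, highest other 1) and 1 of 10 as many lists (real 14, highest other 9). At 1 h against untreated the numbers were 10 of 10 for rows (real 0, highest other 0) and 2 of 10 for lists (real 13, highest other 14). Between 48 h and 1 h they were 1 of 10 for rows (real 1, highest other 0) and 3 of 10 for lists (real 3, highest other 4). For the F test 14 of 100 splits gave as many rows as the real one (real 1, highest other 3), so chance was not excluded.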

How the results depend on the processing

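Array quality weights, rows naming 1 gene alone, and an estimated correlation without untreated replicate 2 were chosen after seeing the data. No list that passed and no named gene value reversed under any alternative that was run. Among lists that had not passed, the direction of the test turned without untreated replicate 2 for 3 of 17 at 48 h, 5 of 18 at 1 h and 1 of 28 between the times, among them ribosomal proteins at 1 h (median 0.12 to -0.03) and RNA and array quality at 48 h (0.10 to -0.18).

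Rows past the test at 48 h against untreated went from 1 to 0 with the replicate block, with 2 groups alone in the fit and with a plain test, and so did rows at 48 h against 1 h. The F test gave 0 with the replicate block and 2 with quantile normalization. At 48 h against 1 h 2 rows passed with quantile normalization, median centring, the dimmest 25% left out, the intensity trend and robust prior, and array quality weights. With quantile normalization the second row names no gene and was lower (log2 difference -2.57, adjusted p = 0.0157; -2.60 and 0.0571 as deposited). At 1 h 0 rows passed in all of these except the weights. The cause was not tested, except that 2 groups alone leave fewer arrays to estimate the spread.

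With array quality weights 3788 rows passed at 48 h, 1136 at 1 h, 2841 among the probe sets differing among the 3 groups and 860 in the overlap of the 2 treated times, and 5 lists at 48 h against 1 h. The row counts against untreated rest on untreated replicate 1, which took 92.1% of its group's weight; with weights from the 8 arrays other than untreated replicate 2, 0 rows passed at 48 h against untreated, 0 at 1 h against untreated and, as with 9 arrays, 2 at 48 h against 1 h. The F test, the overlap and the lists were not rerun with those weights.

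The replicate numbers were not taken to pair the samples. The sample titles give arrays of the same replicate number the same letter, A, B or C, in all 3 groups. No label says that this letter marks a shared culture, day or batch. Only 6 of 9 pairs, all of replicates 1 and 3, correlated above 0.1 in their deviations from the group means. Those of replicate 2 gave -0.04, 0.03 and 0.06. Still, 7 of 9 arrays correlated best with their own number, a hint of pairing from the data. With the replicate block 0 rows passed in each comparison and in the F test, and 14, 13 and 3 lists passed; SNORD38A had an adjusted p of 0.323 at 48 h against untreated and 0.532 at 48 h against 1 h. Over all alternatives its adjusted p ran from 0.0022 to 0.798 and from 0.0052 to 0.845, with the upper ends from the plain t test without moderation. The highest limma adjusted p were 0.530 and 0.532.

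With an estimated correlation 2, 2 and 0 lists passed at 48 h, at 1 h and between the times. Without untreated replicate 2 as well, the numbers were 0, 1 (DNA replication at 1 h, adjusted p = 0.0491) and 0, so the mitosis and histone calls did not hold under both changes together. Quantile normalization ended the list calls of heat shock and autophagy at 48 h, and of glycolysis, autophagy and metallothioneins at 1 h. Leaving out the dimmest 25% ended those of NF-kB and autophagy at 48 h and of autophagy at 1 h, and 2 groups alone in the fit ended that of NF-kB at 48 h. Array quality weights ended those of the unfolded protein response, cholesterol, NF-kB and autophagy at 48 h and of glycolysis at 1 h.

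Leaving out each array in turn gave 0 to 0 rows at 48 h against untreated, 0 to 2 at 48 h against 1 h and 0 to 0 in the F test. Lists ranged from 9 (without untreated replicate 3) to 14 at 48 h and from 8 (without untreated replicate 1) to 14 at 1 h. Of 540 list values recomputed, 432 kept their side of the threshold and their direction and 108 no longer passed. Of 2549 values of named genes, 2438 kept both, 88 came to pass and 23 no longer passed. Only SNORD38A had passed in the main fit, so most values kept their side by again not passing. Apart from array quality weights no setting called more than 2 rows in a comparison, so the 88 came mainly from the weighted fit. An alternative floor was not run, since the values were already logarithms. Background signal is not given, so what it limits could not be measured.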

Other observations

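Small nucleolar RNAs, many of which guide the modification of ribosomal RNA, had lower signal at 1 h than in the untreated group as a whole. Of 173 rows 137 were lower and 36 higher, with a median log2 difference of -0.23 (limma camera, unadjusted p = 3.1e-11, and 0.0727 with an estimated correlation). Rows of microRNA genes were lower in the same comparison, 115 of 173, with a median of -0.11 (unadjusted p = 1.8e-04, and 0.169 with an estimated correlation), so the shift was not confined to small nucleolar RNAs. At 48 h the median against untreated cells was -0.06, with 97 lower and 76 higher (unadjusted p = 0.881). Untreated replicate 2 had the highest median deviation of the small nucleolar RNA rows, at 0.27, against -0.01 and -0.10 on the other untreated arrays. The values were -0.09, -0.09 and -0.21 at 1 h and 0.00, 0.03 and -0.02 at 48 h. Untreated replicate 3 thus lay below 1 h replicates 1 and 2. The test was not rerun without untreated replicate 2, so how far the fall at 1 h rests on that array was not tested. Box H/ACA members, 61 rows, and box C/D members, 112 rows, had medians of 0.16 and 0.15 at 48 h against 1 h. These groups of rows were chosen after SNORD38A had been seen.

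Among genes outside the naming rule, chosen after their values were seen, GADD45A, a growth arrest gene induced by DNA damage, measured 5.18 ± 0.23 in untreated cells, 5.69 ± 0.19 at 1 h and 6.24 ± 0.26 at 48 h (log2, SD, n = 3). TIPARP, a target of the aryl hydrocarbon receptor, measured 4.24 ± 0.50 in untreated cells and 5.05 ± 0.54 at 1 h, with a difference of 1.36 ± 0.31 (SE) at 48 h. At 48 h against untreated these 2 passed when adjusted over the list alone, the p53 and the AhR list (limma, adjusted p = 0.00961 and 0.0275), while neither list passed and neither gene passed over all rows (adjusted p = 0.441 and 0.602).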
